A study of Homo sapiens with 6 samples.

How the data were processed

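Gene expression was measured with an Affymetrix array in 6 samples of TE-1, a human cell line derived from an oesophageal squamous cell carcinoma. Per the labels, EIF3C was stably knocked down, RNA came from the knockdown clone and from the parental cells as control, and each group has 3 biological replicates. Total RNA was extracted with Trizol and labelled with biotin, per the labels' protocols. The labels do not say whether replicates came from separate cultures, and the 3 knockdown samples share 1 clone. The p-values therefore measure only the spread between these samples, which may be technical. A clone picked after selection can differ from its parental line for reasons other than the knockdown, and the labels describe no further clone and no cells with a control construct.

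The values used were the table of log2 signals deposited by the authors, with 1 column per array and 49395 probe sets. MAS5 is named as the software, per the submitters' processing notes, and no version is recorded. Background correction, summarisation of probes into probe sets and the log step are not given in the sources used here. The log2 scale was inferred from the values, which ran from 1.99 to 14.1 over the arrays, with array medians between 6.09 and 6.11 and no negative value. From the narrow range of the medians the arrays were taken as already scaled to each other, so the signals were used without further normalization. A change shared by all genes would be removed by such scaling and cannot be measured here. Detection calls and scanner files were not used here, so a dim probe set cannot be called absent, and folds of dim probe sets are uncertain. The number of arrays limits the precision.

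Probe sets were named from the platform annotation. Of the human probe sets, 44988 carried 1 gene symbol, 1832 carried several and 2473 carried none, and a further 102 probe sets were array controls. Of the probe sets with 1 symbol, 44961 were matched by Entrez ID to a RefSeq gene table of GRCh38.p14 and 27 were not, and the match changed 0 symbols. The gene table served only for names and for which genes neighbour each other, and no coordinates are given because no build was named for the array. Only probe sets with 1 symbol were used for gene results, and each gene was represented by the probe set with the highest mean over all 6 arrays. This gave 18132 genes. The lowest 25% by mean were left out, which set the lowest mean kept at 4.635 and left 13599 genes to test. Probe sets of EIF3C are all shared with EIF3CL, a nearly identical gene, so the target was taken from a separate fit over all 49293 human probe sets without a filter.

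Knockdown was compared with control by limma 3.58.1 in R 4.3.3, with lmFit and eBayes with an intensity trend, group as the only term and Benjamini-Hochberg adjustment over all genes tested. The threshold was an adjusted p of 0.05, and a change of at least 2-fold was counted separately. All adjusted p-values of genes come from this test. For 35 gene lists, made up of 30 pathway or cell state lists and 5 lists of markers of other cell types, members past the threshold were counted with adjustment over all genes and adjusted over the list alone. Each list was also tested against the remaining genes with limma's camera at a preset correlation of 0.01, adjusted over the lists, and with camera at an estimated correlation and with fry as alternatives. The cystine transporter gene SLC7A11 stands in the lists of both ATF4 and NRF2 targets. The lists, the tests, the rule for naming genes and the other settings were fixed before the data were examined.

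Genes were named by rule. The named genes were EIF3C with all its probe sets, every eIF3 subunit, and ACTB and GAPDH as array control genes. To these were added the 12 largest rises and 12 largest falls among genes past the threshold, with no overlap between the groups and a mean in the higher group at or above the median of all tested genes, 7.61. Of the rises, 1 is not reported here. Uncharacterised loci, open reading frames and pseudogenes were skipped in that part. For each list, up to 4 members with the largest change among those past the threshold were named, or the 2 with the smallest adjusted p where fewer than 2 passed.

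The test was checked on simulated data built on the spread of these 13599 genes, with 200 genes changed in each of 10 draws. It recovered 48.8% of changes of 0.25, 87.3% of changes of 0.5 and 99.7% of changes of 1 on the log2 scale, and 3.29% of its calls were false. The simulated genes varied independently and few were changed, whereas 66.5% of genes passed in the data. These shares therefore need not hold for the real comparison, and a shift shared by a group was not simulated. Alternatives were no filter, a filter at 50%, quantile normalization, median centring, the mean of a gene's probe sets, every probe set on its own, eBayes without the trend, robust eBayes, array weights, the replicate number as a block, and each array left out in turn. The labels name no batch or scan date. No pair of arrays held identical values: 0 pairs did so.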

Results

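The series compared gene expression in TE-1 cells with a stable knockdown of EIF3C with that of the parental cells. EIF3C encodes a subunit of eIF3, the complex that helps to bring the small ribosomal subunit to mRNA at the start of translation. Each group had 3 arrays. Median log2 signals lay between 6.09 and 6.11 in every array. Correlations across probe sets were 0.9977 to 0.9985 within groups and 0.9823 to 0.9846 between groups.

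EIF3C itself was lower in each of the 3 knockdown samples than in any control. Of 5 probe sets assigned to EIF3C and its near-identical copy EIF3CL, 3 were bright, with control means above 10. On the brightest the log2 signal was 10.62 ± 0.06 in control and 8.44 ± 0.04 in knockdown (mean ± SD, n = 3 each), which left 22.1% of the control level (limma with Benjamini-Hochberg, adjusted p = 6.58e-15). The other bright probe sets left 21.5% and 22.6%. The remaining probe sets were dim in both groups, at 4.39 and 4.53 in control, with changes of -0.58 and -0.97. None of the 5 probe sets separates EIF3C from EIF3CL, so the values are the sum of both genes.

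**Figure D1:**
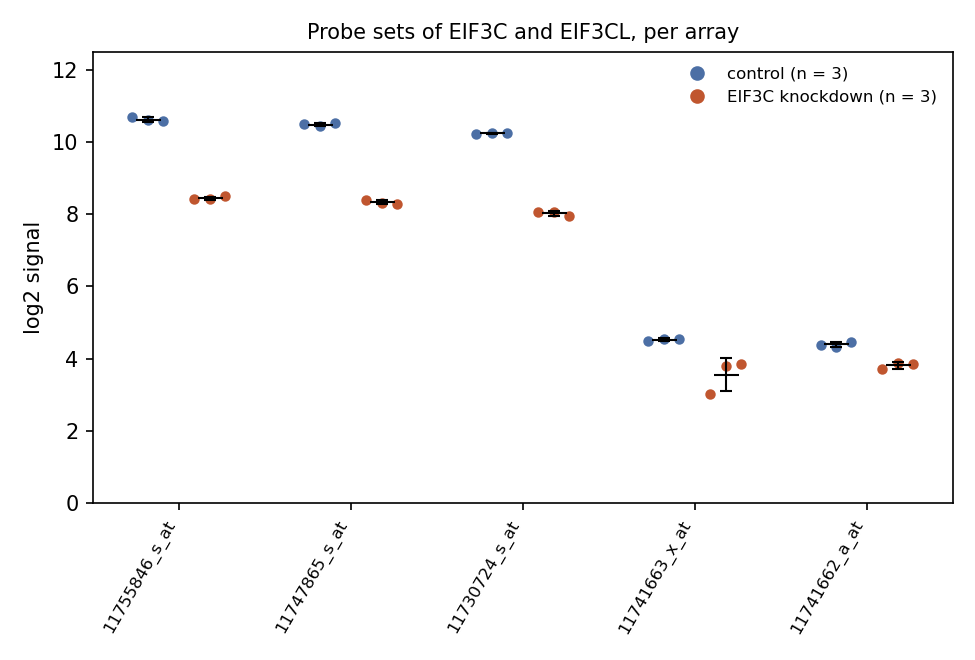
Log2 signal of the 5 probe sets of EIF3C and EIF3CL on each array, with 3 control arrays in blue and 3 knockdown arrays in orange; horizontal lines are group means and error bars SD. The 3 bright probe sets fell from control means above 10 to between 8.02 and 8.44, and the dim ones lay below 5 in both groups.

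Knockdown cells had much higher transcript levels of AXL, IL6, PLAU and EREG and much lower levels of SLC40A1, CCNG1, COL1A2 and PSAT1. AXL, a receptor tyrosine kinase, rose from 7.35 ± 0.10 to 10.27 ± 0.02 (mean log2 signal ± SD, n = 3 each), a 7.58-fold difference (SE 0.05 on the log2 scale, adjusted p = 1.88e-17). The cytokine IL6 rose 7.54-fold, from 6.34 ± 0.05 to 9.25 ± 0.03 (adjusted p = 2.85e-17), and PLAU, the urokinase plasminogen activator, rose 7.26-fold, from 6.57 ± 0.08 to 9.43 ± 0.04 (adjusted p = 4.97e-17). SLC40A1, the iron exporter ferroportin, had the largest named fall, from 7.79 ± 0.16 to 4.04 ± 0.10 (adjusted p = 1.41e-15). Its knockdown level lay below 4.635, the lowest mean kept for testing, so its 13.5-fold difference is uncertain. PSAT1, an enzyme of serine synthesis, fell from 11.64 ± 0.07 to 9.41 ± 0.02, a 4.69-fold difference seen on 8 of its 8 probe sets (adjusted p = 9.03e-18).

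The other large rises were those of the scavenger receptor family gene CD163L1 (log2 fold change 2.95), the G protein subunit GNA15 (2.88), the EGFR ligand EREG (2.68), FAM216A (2.63), BTF3L4 (2.61), MZT1 (2.52), RHEBL1 (2.25) and the AP-1 subunit FOSL1 (2.19). The other large falls were those of STON1 (-3.03), the p53-responsive gene CCNG1 (-2.81), the type I collagen chain COL1A2 (-2.52), the amino acid transporter subunit SLC7A7 (-2.51), the immune checkpoint ligand VTCN1 (-2.49), the desmosomal cadherin DSC2 (-2.38), USP46 (-2.23), SMIM14 (-2.21), HDDC2 (-2.01) and FBXW2 (a 3.99-fold difference). The genes named here passed the threshold, with no overlap between the groups. Adjusted p was at most 8.6e-13 among them. Probe sets of a gene differed in size: EREG ranged from 0.39 to 2.68 over 4 probe sets and a further probe set of FBXW2 stood at 0.07.

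**Figure D2:**
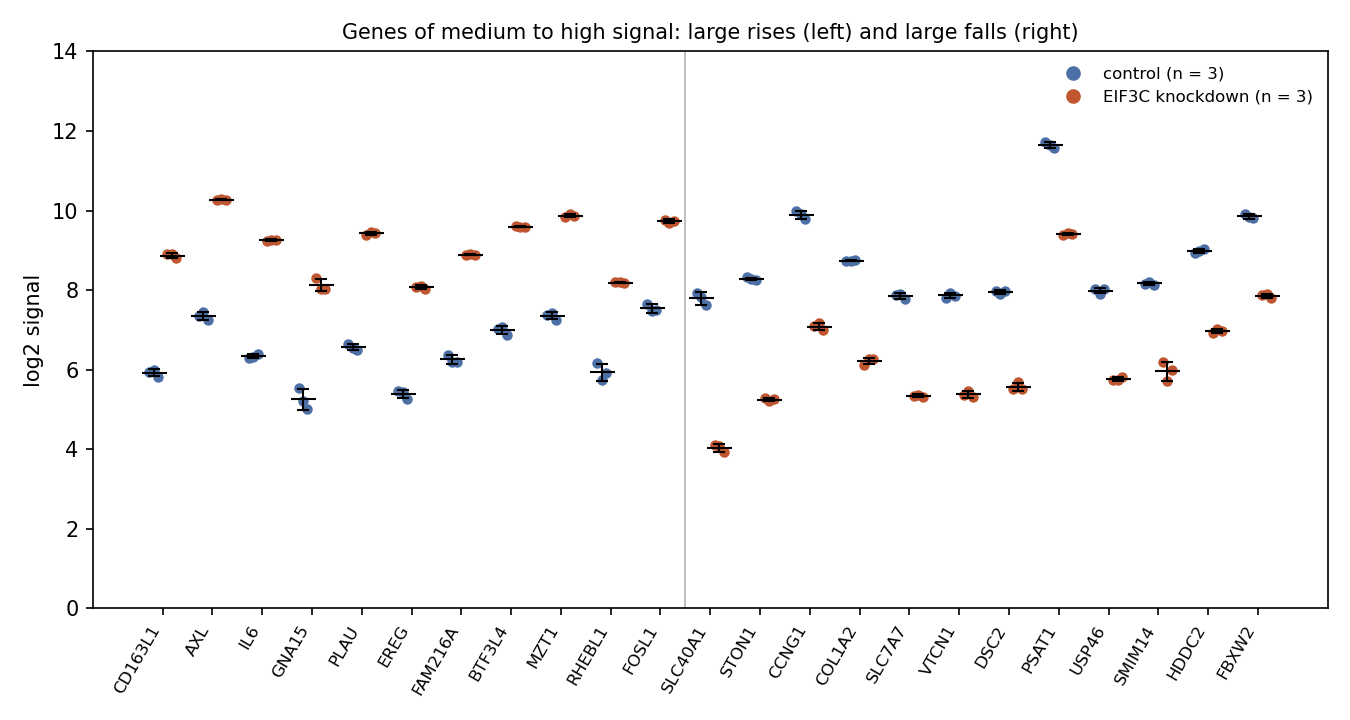
Log2 signal on each array for the named large rises (left) and large falls (right) among genes whose higher group mean was at or above 7.61; blue points are the 3 control arrays, orange points the 3 knockdown arrays, lines are means and error bars SD. The groups do not overlap for any of these genes, and SLC40A1 ends at 4.04, the lowest mean shown.

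Across the 13599 genes tested, 9037 passed the threshold, 4401 higher and 4636 lower in knockdown. At least 2-fold changes were found for 655 genes, 353 higher and 302 lower, and at least 4-fold changes for 29 higher and 16 lower genes. Many calls were small: 3936 called genes changed by less than 1.25-fold. The groups did not overlap for 70.3% of genes, where chance gives 10%. The 85 non-human control probe sets differed between the groups by -0.22 to 0.20, and 23.7% of the called genes changed by no more than the largest of these differences. When the probe sets of a gene were averaged, 428 genes changed at least 2-fold, and 765 of 6800 called genes with more than 1 probe set had another probe set called the opposite way.

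Every tested ribosome biogenesis gene rose. All 30 of 30 passed, both over all genes and adjusted over the list alone, with a median log2 fold change of 0.50 (camera adjusted p = 7.79e-11; adjusted p = 0.341 with an estimated correlation). DKC1, the pseudouridine synthase of box H/ACA particles, rose by 1.57, the box C/D protein NOP58 by 1.09, WDR43 by 0.99 and GAR1 by 0.92. Other translation initiation factors also rose more often than they fell, 16 against 6 of 24 and likewise adjusted over the list alone (median 0.25, camera adjusted p = 0.0222; adjusted p = 0.623 with an estimated correlation). EIF2B1 rose by 1.60, EIF2S1 by 1.38 and EIF5 by 1.30, while EIF4EBP1, a repressor of eIF4E, fell by 0.77. This set call was lost with a 50% filter (adjusted p = 0.0713) and with the mean of a gene's probe sets (adjusted p = 0.0872).

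The other subunits of eIF3 changed little in size. Of 12 tested, 8 rose and 3 fell, also adjusted over the list alone, and the list as a whole did not pass (median 0.13, camera adjusted p = 0.105). EIF3J rose by 0.71, EIF3G by 0.67, EIF3M by 0.45, EIF3I by 0.22, EIF3D by 0.20, EIF3A by 0.17, EIF3K by 0.09 and EIF3B by 0.06. EIF3F fell by 0.34, EIF3L by 0.11 and EIF3E by 0.05, and EIF3H, at 0.04, did not pass (adjusted p = 0.127). The changes of EIF3D, EIF3A, EIF3K, EIF3B, EIF3L and EIF3E were smaller in size than the largest difference of a non-human control probe set, 0.22. That was a fall of a dim probe set, at 3.73 in control. The largest rise of a control was 0.196, just under that of EIF3D. Among brighter controls, an antigenomic probe set at 10.60 in control fell by 0.20 and hybridisation spikes differed by -0.15 to 0.10. A technical shift can therefore not be excluded for these subunits. EIF3G ranged from -0.14 to 0.67 over 4 probe sets, 2 of them called higher. The calls of EIF3B, EIF3E and EIF3K were lost without the intensity trend, and that of EIF3E also with median centring and with any of 4 arrays left out, namely control replicates 2 and 3 and knockdown replicates 1 and 2. Without control replicate 3 (adjusted p = 0.0567) or knockdown replicate 3 (0.0813), EIF3B did not pass. Among cytosolic ribosomal proteins, 20 of 64 rose and 30 fell, or 20 and 31 adjusted over the list alone (median -0.03, camera adjusted p = 0.386). RPL35A rose by 1.36 and RPL35 by 0.53, and RPS28 fell by 0.82 and RPL13 by 0.70. A further probe set of RPL35A went the opposite way, at -0.53. Without the intensity trend, 12 ribosomal protein genes were higher.

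Genes responsive to ERK signalling and ligands of EGFR rose. Of 24 tested, 18 rose, 14 of them at least 2-fold, and 4 fell, with the same counts adjusted over the list alone (median 1.04, camera adjusted p = 3.19e-06; adjusted p = 0.369 with an estimated correlation). Besides EREG and FOSL1, the ERK phosphatase gene DUSP4 rose by 1.87 and PHLDA1 by 1.60. Heat shock genes rose in 13 cases of 19 and fell in 3, also adjusted over the list alone (median 0.37, camera adjusted p = 0.00023; adjusted p = 0.341 with an estimated correlation). HSPA4L rose by 1.22, the HSP90 co-chaperone FKBP4 by 1.15, CHORDC1 by 0.80 and HSPH1 by 0.78. Without control replicate 2, or with the mean of a gene's probe sets, 1 heat shock gene fell. Proteasome subunits rose in 22 cases of 27 and fell in 3, also adjusted over the list alone (median 0.17, camera adjusted p = 0.000217; adjusted p = 0.341 with an estimated correlation). PSMC3 rose by 0.88, PSMD12 by 0.71 and PSMC4 by 0.57, and the core subunit gene PSMA1 fell by 1.12. A further probe set of PSMD12 was called lower, at -0.17, and that of PSMA1 stood at -0.14 and was not called. The median of the proteasome list lay within the largest difference of a single non-human control probe set, 0.22.

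Among genes of G1/S and DNA replication, 23 of 33 rose and 6 fell, also adjusted over the list alone (median 0.27, camera adjusted p = 0.00141; adjusted p = 0.508 with an estimated correlation). DTL rose by 0.88, HELLS by 0.85, the clamp loader subunit gene RFC2 by 0.71 and RRM2, a subunit of ribonucleotide reductase, by 0.61. Genes of G2/M and mitosis went both ways, with 23 of 37 higher and 9 lower, also adjusted over the list alone (camera adjusted p = 0.0796). Cyclin A2 (CCNA2) fell by 1.03, KIF20A by 0.98 and CDC25B by 0.75, while BIRC5, or survivin, rose by 0.88. Of replication-dependent histones, 7 of 12 rose and 4 fell, also adjusted over the list alone (camera adjusted p = 0.523). H2AC6 rose by 0.74, H1-2 by 0.74 and H1-3 by 0.50, and H2BC21 fell by 0.82. For H2BC21, 1 of 3 probe sets was called. With a 50% filter, 3 histone genes rose.

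Target genes of ATF4 in the integrated stress response fell. Of 28 tested, 22 fell, 8 of them at least 2-fold, and 4 rose. Adjusted over the list alone, 23 fell and 4 rose (median -0.62, camera adjusted p = 7.86e-06; adjusted p = 0.35 with an estimated correlation). Besides PSAT1, the asparagine synthetase gene ASNS fell by 1.70, DDIT4 by 1.50 and PHGDH, the first enzyme of serine synthesis, by 1.41. Chaperones and other genes of the unfolded protein response fell in 16 cases of 20 and rose in 2, also adjusted over the list alone (median -0.38, camera adjusted p = 0.000357; adjusted p = 0.341 with an estimated correlation). The co-chaperone gene DNAJC3 fell by 1.19, SDF2L1 by 0.60 and the disulfide isomerase gene PDIA6 by 0.51, and DNAJB9 rose by 0.69.

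**Figure D3:**
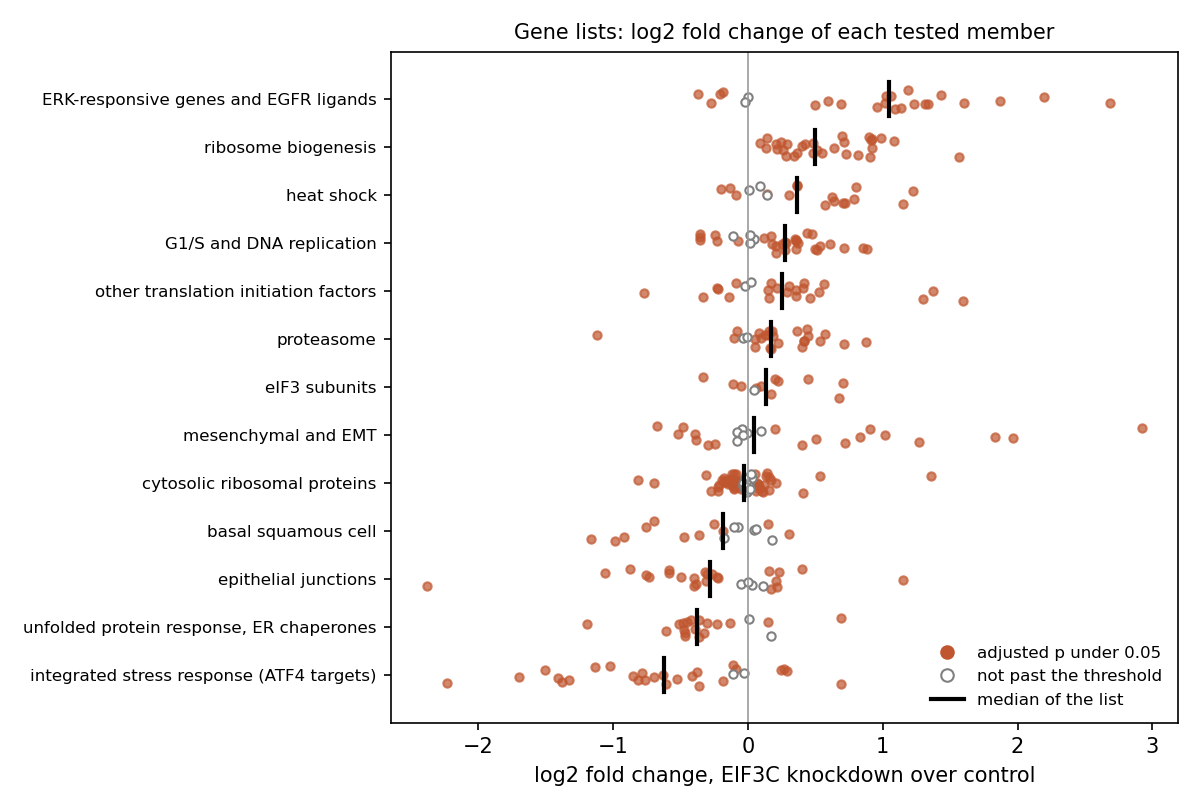
Log2 fold change of each tested member of 13 gene lists, knockdown over control; filled points passed the threshold, open points did not, and black bars are list medians. Medians run from 1.04 for ERK-responsive genes down to -0.62 for ATF4 targets, and no ribosome biogenesis gene lies below 0.

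Genes of epithelial junctions fell more often than they rose. Of 28 tested, 17 fell and 7 rose, or 17 and 8 adjusted over the list alone (median -0.28, camera adjusted p = 0.0473; adjusted p = 0.655 with an estimated correlation). DSC2 fell by 2.38, the membrane protease gene ST14 by 1.06 and RAB25 by 0.87, and the tight junction gene CLDN1 rose by 1.15. This set call was lost with a 50% filter (adjusted p = 0.0686), the mean of a gene's probe sets (0.0909), no intensity trend (0.0936) and without control replicate 1 (0.0569). Basal squamous genes did not pass as a list, with 9 of 17 lower and 2 higher, also adjusted over the list alone (camera adjusted p = 0.0796). ITGA6, an integrin chain of hemidesmosomes, fell by 1.16, TRIM29 by 0.99, KRT15 by 0.92 and DSC3 by 0.76. Without control replicate 3, 4 basal genes were higher, and with array weights 5 were. Squamous differentiation genes did not pass either, with 6 of 20 lower and 3 higher, also adjusted over the list alone (camera adjusted p = 0.676). SCEL, or sciellin, fell by 2.40, KLK13 by 0.39 and CNFN by 0.39, and EMP1 rose by 0.33. With no filter, 10 squamous differentiation genes were lower, and with a 50% filter 1 was.

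Mesenchymal genes were split. Of 24 tested, 11 rose, 5 of them at least 2-fold, and 7 fell, also adjusted over the list alone (median 0.05, camera adjusted p = 0.172). Besides AXL, the tropomyosin gene TPM2 rose by 1.96, the ectonucleotidase gene NT5E by 1.83 and SNAI2, a repressor of epithelial genes, by 1.27. Among matrix proteases and invasion genes, 7 of 22 rose and 11 fell, also adjusted over the list alone (camera adjusted p = 0.523). PLAU and the hyaluronan receptor gene CD44 rose, CD44 by 1.02, while the inhibitor gene TIMP2 fell by 1.59 and the membrane protease gene MMP14 by 1.26. A further probe set of TIMP2 rose by 0.25. Among genes of the TGF-beta pathway, 9 of 26 rose and 15 fell, also adjusted over the list alone (camera adjusted p = 0.506). The receptor gene TGFBR2 rose by 1.87 and BMP2 by 1.43, and BMPR2 fell by 1.15 and PMEPA1 by 1.07, although a further probe set of PMEPA1 was called higher, at 0.17.

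In the list of NF-kB and inflammatory cytokine genes, 9 of 19 rose and 0 fell, also adjusted over the list alone (median 0.07, camera adjusted p = 0.076). Besides IL6, the related cytokine LIF rose by 1.51, the adhesion molecule ICAM1 by 0.57 and RELB by 0.44. Without control replicate 1 or knockdown replicate 1, 1 gene of the list was lower, as it was with the mean of a gene's probe sets and without the intensity trend. Interferon-stimulated genes fell in 11 cases of 25 and rose in 5, also adjusted over the list alone (camera adjusted p = 0.517). SAMD9 fell by 1.06 and IFI6 by 0.88, and the immunoproteasome gene PSMB8 rose by 0.98 and the RNA sensor gene RIGI by 0.90. Among apoptosis regulators, 14 of 29 rose and 10 fell, also adjusted over the list alone (camera adjusted p = 0.253). The death receptor genes FAS and TNFRSF10A rose by 2.09 and 1.41, and the BH3-only genes BIK and PMAIP1 by 1.06 and 0.84.

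Metabolic lists did not pass as wholes. Glycolysis genes rose in 8 cases of 18 and fell in 3, also adjusted over the list alone (camera adjusted p = 0.105), with HK2 up by 1.60, PFKP by 0.89, ALDOA by 0.61 and ENO2 by 0.55. A further probe set of HK2 stood at 0.20 and was not called. Without control replicate 3, 5 glycolysis genes were lower. Oxidative phosphorylation genes fell in 17 cases of 34 and rose in 11, or 17 and 12 adjusted over the list alone (camera adjusted p = 0.172). UQCRQ fell by 0.80, UQCRC1 by 0.66, NDUFS3 by 0.63 and NDUFA1 by 0.61. A further probe set of NDUFS3 stood at 0.17 and was not called. Hypoxia and angiogenic factor genes rose in 11 cases of 23 and fell in 8, also adjusted over the list alone (camera adjusted p = 0.369), and their median of 0.05 turned to -0.01 with quantile normalization. FGF2 rose by 1.91, adrenomedullin (ADM) by 1.31 and PFKFB3 by 1.30, and PFKFB4 fell by 0.88. With a 50% filter, 5 genes of this list fell. Cholesterol synthesis genes rose in 6 cases of 19 and fell in 9, also adjusted over the list alone (camera adjusted p = 0.523), with SQLE up by 1.05 and PMVK by 0.73, and with falls of INSIG1 by 0.93 and SREBF2, where the log2 signal fell by 0.79. NRF2 targets rose in 7 cases of 22 and fell in 10, also adjusted over the list alone (camera adjusted p = 0.771). Their median of 0.03 had the opposite sign to the mean of -0.05 and to camera's direction, and turned to -0.01 with quantile normalization. ABCC3 rose by 1.04 and PIR by 0.80, and HMOX1, which degrades haem, fell by 0.98 and AKR1C2 by 0.84. For AKR1C2, 1 of 3 probe sets was called.

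Lists of exosome secretion, autophagy and lysosome, WNT and NOTCH genes did not pass either. Exosome secretion genes fell in 13 cases of 23 and rose in 8, also adjusted over the list alone (camera adjusted p = 0.523). RAB11A fell by 1.07 and RAB7A by 0.73, and VAMP7 rose by 1.09 and RAB27A by 0.71. RAB27A had a further probe set called lower, at -0.18, and its call was lost with the mean of its probe sets. Autophagy and lysosome genes fell in 13 cases of 27 and rose in 11, also adjusted over the list alone (camera adjusted p = 0.523), and the kinase gene ULK1 fell by 0.82, CTSA by 0.75, NEU1 by 0.68 and CTSD by 0.67. Genes of the WNT pathway fell in 12 cases of 23 and rose in 5, also adjusted over the list alone (camera adjusted p = 0.115). ZNRF3 fell by 1.30, FZD1 by 1.05 and WNT10A by 0.89, and LEF1 rose by 0.83. Without control replicate 3, knockdown replicate 1 or knockdown replicate 3, and with a 50% filter, 3 WNT genes rose. Genes of the NOTCH pathway fell in 6 cases of 22 and rose in 3, also adjusted over the list alone (camera adjusted p = 0.517). NOTCH3 fell by 1.11, DTX3L by 0.85 and JAG1 by 0.73, and the ligand gene DLL1 rose by 1.01. For NOTCH3, 1 of 2 probe sets was called, and for DLL1 1 of 3.

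Markers of other cell types did not move together. Among fibroblast markers, 2 of 7 tested rose and 4 fell (camera adjusted p = 0.523), with COL1A2 down by 2.52, while MFAP5 fell by 0.52 and FBLN1 by 0.34. COL5A1 rose by 0.24 but had a value of -0.07 with the mean of its probe sets. Endothelial markers were higher in 1 case of 7 and lower in 2 (camera adjusted p = 0.694), where CDH5 rose by 0.46, EGFL7 fell by 0.54 and KDR fell by 0.26. The call of KDR was lost with array weights and without control replicate 3 (adjusted p = 0.147), knockdown replicate 2 (0.111) or knockdown replicate 3 (0.0747), which left 1 endothelial marker lower. Leukocyte markers were higher in 2 cases of 9 and lower in 1 (camera adjusted p = 0.859), where CORO1A rose by 0.32, ITGB2 rose by 0.31 and LCP1 fell by 0.51. Without control replicate 1 or 2, 2 leukocyte markers were lower, as with the replicate number as a block, and with the mean of a gene's probe sets 3 were. Of glandular epithelium markers, 2 of 7 fell and 0 rose (camera adjusted p = 0.482), namely GATA6 by 1.11 and AGR2, which fell by 0.72. With the mean of a gene's probe sets, 1 glandular marker was higher and 1 lower. Of 4 hepatocyte markers, 0 passed (camera adjusted p = 0.705), and the smallest adjusted p were those of APOC3 at -0.20 (0.16) and TF at -0.13 (0.214). Without knockdown replicate 3, APOC3 passed, at -0.32 (adjusted p = 0.0246). With a 50% filter, 2 fibroblast markers were lower, 0 endothelial markers higher and 1 lower, 1 leukocyte marker higher and 0 lower, and 1 glandular marker lower. With no filter, 1 hepatocyte marker was higher. Counts for these 5 lists were the same adjusted over the list alone.

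Of the array control genes, ACTB rose by 0.216 (adjusted p = 3.56e-09), with 1 of its 3 probe sets called and the lowest at 0.01. The largest difference of a non-human control probe set, 0.221, was a fall of a dim absent sequence, and the largest rise was 0.196. The cre spikes, about as bright as ACTB, differed by -0.02 to 0.05. Separate actin control probe sets of the array rose by 0.12, 0.17 and 0.21 (limma adjusted p at most 4.12e-05). GAPDH did not pass, at -0.03 (adjusted p = 0.151), and stood at 0.03 with quantile normalization. The difference between 3' and 5' probe sets, a sign of RNA quality, was 0.555 ± 0.076 in control and 0.504 ± 0.014 in knockdown for ACTB, and 0.062 ± 0.013 and 0.064 ± 0.012 for GAPDH (log2, mean ± SD, n = 3 each).

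In all, camera called 9 of the 35 lists, 6 up and 3 down. With an estimated correlation, 0 lists were called at an adjusted p of 0.05 and 5 had an unadjusted p under 0.05, and the lowest adjusted p was 0.341. By fry, which asks whether a list's genes move on balance in a single direction and does not compare them with other genes, 30 lists were called.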

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

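The tests on control probe sets, on neighbouring genes, on genes of matched signal and on fibroblast markers were chosen after the results they bear on had been seen.

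Probe sets outside the gene comparison also changed at least 2-fold, well beyond the range of the non-human controls, -0.22 to 0.20 on the log2 scale. Of 2473 probe sets with no gene symbol, 80 did so, 44 higher and 36 lower in knockdown (limma with Benjamini-Hochberg, adjusted p under 0.05). Of 1832 probe sets with several symbols, which include those of EIF3C, 52 did so, 22 higher and 30 lower. Of 4533 genes left out as dim, 18 did so, 10 higher and 8 lower.

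The share of genes that passed, 66.5%, is large for 3 arrays per group. A technical shift that also moved the non-human control probe sets is argued against as the whole cause, since 23.7% of called genes changed by no more than the largest difference of such a probe set. The controls are not part of the cells' RNA, so they cannot show a group difference from culture or RNA extraction. For the 2141 called genes within that difference, a technical shift cannot be told apart from a biological change. Of 18 hybridisation spike probe sets, which spanned -0.15 to 0.10, 16.7% were called (95% Clopper-Pearson interval 3.58% to 41.4%), and of all 85 controls 4.71%. Of 6670 genes with changes up to 0.22 in size, 32.1% were called. The controls were called in a fit over all 49395 probe sets, so these shares differ in setting. Most called genes did not lie in windows of neighbouring genes whose median shifted beyond shuffled orders. This argues against gains or losses of large regions as their direct cause where these shift signal that far. Windows of 51 neighbouring genes whose running median passed the 95th or 5th percentile of the extremes of 100 shuffles held 0.62% of called genes. The count covers only genes inside such windows, so it cannot show effects of an altered region on genes elsewhere. Extremes of the shuffles reached 0.305 and -0.28, so a gain or loss with a smaller effect on signal would not be counted and stays open. The 6 arrays make 10 splits, too few for a share under 0.05, and 1 of the 10, the real one, gave as many calls: 9037 against at most 0 in the others, which gave 37 to 133 genes at an unadjusted p under 0.05. Every other split mixes control and knockdown arrays, so the difference between the groups adds to its spread and keeps its calls low. The splits therefore cannot decide on chance. Loss of EIF3C, other differences between a selected clone and its parental line, and group differences in culture or RNA extraction all stay open, and the design does not separate them.

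ATF4 targets fell, with a median of -0.62. Scaling between the arrays is argued against as the cause, because it would act alike on genes of the same signal, and 1000 lists drawn from genes matched to the targets on mean signal had medians around 0.0099 (central 95% of draws -0.14 to 0.18). Lower output of ATF4 may account for the fall: a list of 18 further tested ATF4-responsive genes, written before its test, had a median of -0.29 (95% bootstrap interval -0.46 to -0.01), with 13 lower and 5 higher (camera p = 0.0167; p = 0.186 with an estimated correlation). The ATF4 transcript itself, a value chosen after it was seen, fell by 0.19 (limma adjusted p = 3.4e-07). The largest fall of a non-human control probe set was 0.22, on a dim probe set, and a bright antigenomic one fell by 0.20. A technical shift can therefore not be excluded for ATF4. The further list was tested on the same arrays in which the pattern was found, so lower output of ATF4 remains a hypothesis. Loss of EIF3C and other differences of the clone stay open as reasons for such a change.

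ERK-responsive genes rose, with a median of 1.04. Fibroblasts mixed into the knockdown cultures are argued against: the 14 measured fibroblast markers had a median difference of -0.13 (95% bootstrap interval -0.25 to 0.13), the abundant fibroblast transcripts COL1A2, COL3A1 and DCN stood at 6.22, 3.14 and 3.73 in knockdown against 8.74, 3.39 and 3.60 in control, and COL6A1, the brightest marker, differed by 0.23. FAP went the other way, from 3.88 in control to 4.72 in knockdown, below the dim filter in its mean. A wider programme of AP-1 and TEAD factors was tested with 17 targets of YAP and TEAD, whose median of 0.059 (95% bootstrap interval -0.22 to 0.38, 8 higher and 5 lower) leaves that explanation open in both directions. That list shared no gene with the other lists, and targets of AP-1 were not tested as a list of their own. Loss of EIF3C and other differences of the clone stay open here too.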

How the results depend on the processing

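The count limited to genes beyond the range of the control probe sets was chosen after seeing the data; it left 6896 genes, 3396 higher and 3500 lower. Of 160 named genes, 156 passed the threshold, and over 15 settings 2348 of 2366 alternative values kept their direction and side of the threshold, 15 lost the call, 1 gained it and 2 turned sign: GAPDH, at 0.026 with quantile normalization and past the threshold in neither setting, and COL5A1, at -0.073 with the mean of a gene's probe sets (adjusted p = 0.0649), where other probe sets of the gene were lower. Most named genes were chosen for large changes past the threshold, so their stability does not extend to the other called genes. Of 1050 counts of list members, 1014 stayed within 1.5 times the count reported and 36 did not. Quantile normalization called 9017 genes, 8636 of them among the 9037. The mean of a gene's probe sets called 8736, with 7818 shared, but gave 428 genes changed at least 2-fold against 655, and 159 lower ones against 302; the cause was not tested. Testing every probe set on its own, which adds features by construction, gave 22805 calls, 11587 higher and 11218 lower, and 1665 at least 2-fold, 947 higher and 718 lower. The number of lists called was 14 with no filter and 14 with every probe set, 0 with an estimated correlation, where 5 lists had an unadjusted p under 0.05, and 30 by fry, against 9; the cause was not tested. Leaving out each array in turn gave 8459 to 8890 calls, 4143 to 4349 higher and 4286 to 4572 lower, 653 to 674 at least 2-fold, 332 to 373 higher and 283 to 327 lower, an EIF3C change of -2.21 to -2.15, and 8 to 9 lists, with epithelial junctions lost without control replicate 1. Signal over background limits dim genes, whose folds are uncertain. Pseudocounts of 1 and 64 were not run, because the table is already on a log2 scale.

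With the replicate number as a block (replicate block), 9307 genes were called, 9034 of them shared, with 655 at least 2-fold, an EIF3C change of -2.18 and 9 lists. Deviations of same-numbered arrays correlated at 0.076, 0.129 and 0.227 across genes, and not every array correlated best with its own number, so the numbers were not taken as pairs.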

Other observations

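The values of MYC and the antigenomic control probe sets were chosen after they were seen; the lists of this part were written before their tests.

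Among the further ATF4-responsive genes, 13 of 18 tested fell and 5 rose. The neutral amino acid transporter genes SLC1A4 and SLC1A5 fell by 1.35 and 0.99, the ATF4 partner gene CEBPG fell by 1.01 and the cysteinyl-tRNA synthetase gene CARS1 fell by 0.73, while the threonyl-tRNA synthetase gene TARS1 rose by 0.55 (limma with Benjamini-Hochberg, all past the threshold). Among targets of YAP and TEAD, ANKRD1 rose from 5.74 to 6.74 and GADD45A rose by 0.78, and LATS2 fell by 0.46.

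Ribosome biogenesis genes rose, all 30 of 30. A candidate explanation is higher output of MYC, a transcription factor that drives nucleolar and nucleotide synthesis genes. In a list of 27 other tested MYC-responsive genes of this kind, 2 of which stand in other lists, 21 rose and 1 fell, with a median of 0.32 (95% bootstrap interval 0.13 to 0.52; camera p = 3.2e-06; p = 0.0859 with an estimated correlation). The ornithine decarboxylase gene ODC1 rose by 1.06, POLR3G by 0.94 and the spermidine synthase gene SRM by 0.83. The MYC transcript itself rose from 8.82 ± 0.04 to 9.84 ± 0.04 (mean log2 signal ± SD, n = 3 each; limma adjusted p = 1.19e-13). MYC is also a member of the list of ERK-responsive genes, so its rise was counted there too. The further list holds genes of much the same kind as the ribosome biogenesis list. Any other cause that raised such genes would move both lists, so the test cannot single out MYC. The test was run on the same arrays in which the pattern was found, so higher output of MYC remains a hypothesis, and no technical explanation was weighed for it.

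Of 23 antigenomic control probe sets, the 10 with at most 12 G or C bases were higher in knockdown, by no more than 0.05, and the 13 with at least 13 were lower, down to -0.20; 1 of them, with 25, passed the threshold. The running median of the log2 fold change over 51 neighbouring genes reached 0.27 at its highest and -0.24 at its lowest. In 100 shuffles of the gene order, 1 had a maximum as high and 9 a minimum as low. Medians of whole chromosomes lay between -0.08 and 0.02.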
